A study of Acidipropionibacterium acidipropionici with 4 samples.

How the data were processed

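Gene expression was measured by RNA sequencing in Acidipropionibacterium acidipropionici, a bacterium that ferments sugars to propionic acid. The 4 libraries came from 2 strains, each grown at pH 7.0 and at pH 5.5 and collected in exponential growth. The strains were the wild type CGMCC 1.2230, called the parent here, and WSH1105, an acid-tolerant mutant made by genome shuffling per the labels. Genome shuffling recombines the genomes of several strains by fusing cells. Per the labels' protocols, total RNA was extracted with a column kit after adding lysozyme, and libraries followed a standard Illumina procedure.

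Each of the 4 groups held 1 library. The deposited table had 1 column per library, and each column was assigned to its sample by name. No other column of sample values was present. The table listed 3269 genes with IDs numbered between 0 and 3316, of which 48 numbers were absent.

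The values were read as FPKM, fragments per kilobase of gene scaled to the mapped total of the library, made by the authors before deposition. No source used here states the unit. It was inferred from the header, whose first cell is a name that Cufflinks uses, and from decimal values whose column sums differed between 1498222 and 3157895. Per the submitters' processing notes, Bowtie2 and bedtools 2.16.1 were used, with no roles given. The program that produced the values, the genome build, the annotation, the strandedness of counting and the treatment of reads that map to several places are not given in the sources used here.

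The deposited IDs are not paired with gene names, and no reference annotation was used here. The 30 gene lists fixed before the data were examined (fermentation pathways, acid resistance, chaperones and others) therefore matched 0 genes, and no list was tested. The rule for naming genes, also fixed beforehand, asked for the largest changes, the key members of the lists, and the genes with the smallest adjusted p in the additive fits, each with a product name. No gene met the product-name condition. In its place, at most 2 IDs per direction are given for pH and for strain. These are the genes with the smallest p in the additive fit that were never listed at 0, and this reduction was chosen after the data were seen. In the strain effect, the second lower gene was replaced with the first member of a run of neighbouring IDs.

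Ratios were computed as differences of log2(FPKM + 1), so the change of weakly expressed genes is understated. No scaling was added to the deposited values. Genes with a mean below 10 FPKM over the 4 libraries were left out, which removed 128 and left 3141. With 1 library per group, a ratio of 2 libraries has no replicate error, and it carries no p-value. The ratios compare libraries, and a difference between single cultures cannot be separated from a difference between conditions.

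A test was possible only for the average effect of one factor over the other. An additive model with strain and pH was fitted to the 4 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom per gene. The spread in this fit is the departure from additivity, which holds library noise and any strain-specific pH response together. For each gene, limma moderated this spread with that of other genes, with 5.51 prior degrees of freedom. The SEs and p-values therefore rest largely on other genes, and an SE is not the gene's own reproducibility. On simulated data with 3141 genes built on the pH comparison, the fit recovered 84 of 100 genes changed by 2 on the log2 scale and 100 of 100 changed by 5. It also called 15 unchanged genes for pH, and 3 genes for strain where none had been changed. The simulated recovery does not carry over to the observed data. There, gene2288 with a log2 pH change of -2.52 and gene122 with a log2 strain difference of 2.91 did not pass. A gene that did not pass is therefore not shown to be unchanged.

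Overlaps were set beside the number expected for independent lists, n1 × n2 / N. The pH ratios of the 2 strains share no library, and neither do the strain ratios at the 2 pH values. Genes were ordered by the number in their ID. That these numbers follow the chromosome is not stated in the sources used here. Successive genes are next to each other among the genes kept, so numbers of genes left out can lie between them. Runs of at least 5 genes in this order, counted among genes never listed at 0 unless a 4-fold threshold is named, were compared with 100 shuffles of the order. The alternatives tried were pseudocounts of 0.1 and 5, no filter, 3 other scalings, and limma without the trend. For the scaling to a total without abundant genes, only the 10 most abundant genes were left out, since ribosomal and transfer RNA genes could not be picked out by ID. Leaving out genes listed at 0 in any library, alone or with median-of-ratios scaling, was added after the data were seen. Summaries were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

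An exact 0 in a table of this kind can be a failed estimate. In all 4 libraries 57 genes were listed at 0, and 32 were listed at 0 in some but not all. For the latter no fold change is given. Library depth is unknown. The 80 lowest genes of each pair of libraries were searched for ratios of whole read numbers (up to 8, within 0.05%). In 1 of 6 pairs the best share, 13.8%, exceeded the highest of 20 shuffles, 8.8%, and in the other 5 it did not, so whole reads were not recovered and no counting interval is given.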

Results

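Transcript levels were compared in 4 libraries of Acidipropionibacterium acidipropionici, from the parent strain CGMCC 1.2230 and the acid-tolerant mutant WSH1105, each at pH 7.0 and pH 5.5. Each combination of strain and pH was represented by 1 library. The median gene stood at 159.1 FPKM in the parent at pH 5.5, 166.9 FPKM in the parent at pH 7.0, 158.8 FPKM in the mutant at pH 5.5 and 154.4 FPKM in the mutant at pH 7.0. The upper ends differed more. Each library's own most abundant gene made up 28.5% of the summed FPKM in the parent at pH 5.5, 10.2% in the parent at pH 7.0, 9.68% in the mutant at pH 5.5 and 5.99% in the mutant at pH 7.0. It was not the same gene throughout: in the mutant at pH 5.5 it was gene2708, at 190521 FPKM, and the gene that led the other libraries was listed at 0 there. Across the 3141 tested genes, the 2 pH 5.5 libraries were the most alike (Pearson r = 0.900, Spearman rho = 0.927, on log2 FPKM). The mutant libraries at pH 5.5 and 7.0 were the least alike by Pearson's r, at 0.793. By Spearman's rho, every pair with the mutant at pH 7.0 (0.824, 0.836 and 0.855) was less alike than every pair without it (0.868, 0.883 and 0.927). Pearson's r did not order the pairs in this way. Among genes never listed at 0, the SD of the log2 ratio did. It was 1.174, 1.055 and 1.051 for pairs with the mutant at pH 7.0, and 0.981, 0.980 and 0.724 for pairs without that library. The pH ratio in the mutant, the strain ratio at pH 7.0 and the difference of the pH ratios all use that 1 library. These correlations are across genes, which are not independent replicates. The genes carry only running IDs in the table, so they are described by ID and level.

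The first question was how the parent's transcriptome differed between mildly acidic and neutral medium. In the parent, 383 genes were at least 2-fold higher at pH 5.5 than at pH 7.0 and 311 were at least 2-fold lower, together 22.1% of the genes tested. Among genes never listed at 0, 94 were at least 4-fold higher and 58 at least 4-fold lower. The most extreme of these were 115-fold higher and 56.5-fold lower on the log2(FPKM + 1) scale. Among the same genes, high or low ratios lay side by side. Ratios of genes next to each other in ID order correlated at r = 0.51. The correlation was at most 0.04 in 100 shuffles, and 0.00 for genes 50 places apart in that order. There were 7 runs of at least 5 successive genes that were all at least 2-fold higher, and 9 such runs of lower genes, the longest holding 9 genes in either direction. Shuffled orders gave at most 1 run. The ratio rests on 1 library at each pH and has no replicate check. Of the genes that differed by at least 2-fold, 55.2% were higher, but this share was 35.9% when libraries were scaled to their totals without the 10 most abundant genes.

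The same comparison in the mutant gave more genes. At pH 5.5, 553 genes were at least 2-fold higher and 386 at least 2-fold lower than at pH 7.0, or 29.9% of those tested. Changes of at least 4-fold were found for 106 higher and 81 lower genes never listed at 0. The most extreme of these were 154-fold higher and 30-fold lower. Of the runs of at least 5 successive genes, 12 were higher and 4 were lower, with the longest, of 11 genes, among the higher ones. Shuffled orders gave at most 3 higher runs and 1 lower run. The share of higher genes was 58.9%, and 37.6% with the scaling that leaves out the 10 most abundant genes. The other 2 scalings kept more higher than lower genes, with 57.1% and 56.9% higher in the parent and 54.8% and 56.0% in the mutant. The scaling without the 10 most abundant genes shifts all ratios of a strain by nearly one amount, and it moved the median log2 ratio of all tested genes to -0.26 in the parent and -0.18 in the mutant, from -0.02 and 0.08 as deposited.

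**Figure D1:**
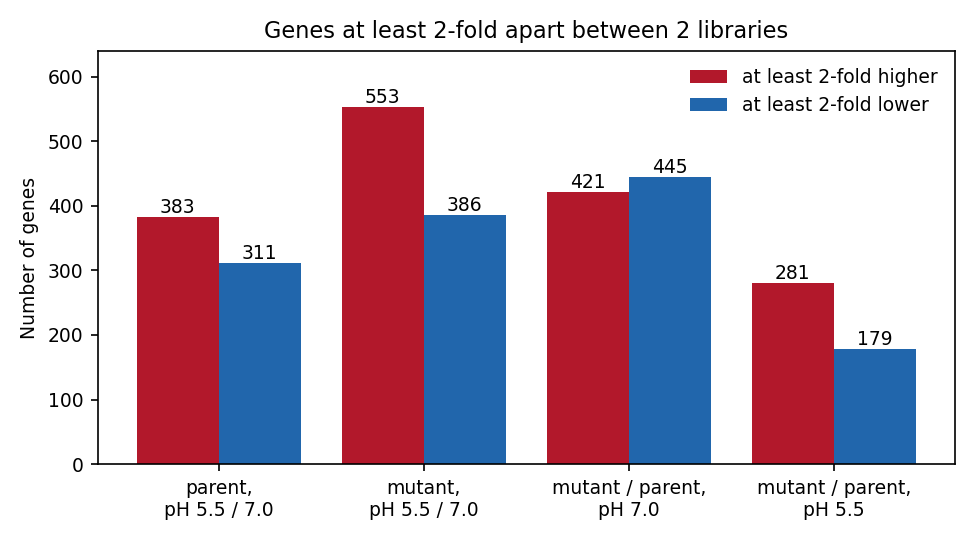
Number of genes (vertical axis, from 0) at least 2-fold higher (red) or lower (blue) in each comparison of 2 single libraries, among 3141 tested genes. The count ranges from 179 genes lower in the mutant at pH 5.5 to 553 genes higher at pH 5.5 in the mutant. There are no error bars because each group held 1 library.

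The lists of genes that differed with pH in the 2 strains overlapped more than independent lists would. At least 2-fold higher at pH 5.5 in both strains were 186 genes, where independent lists of these sizes would share 67.4. At least 2-fold lower in both were 73 genes, against 38.2 for independent lists. Opposite changes of at least 2-fold were seen for 55 genes, against 101.8. The pH ratios of the strains, which share no library, correlated at r = 0.35 (Spearman rho = 0.31) across all tested genes. With the genes in 3 equal groups by mean level, it was 0.28 in the lowest group, 0.42 in the middle group and 0.38 in the highest. Among genes never listed at 0, 14 runs of at least 3 successive genes, 49 genes in all, were at least 2-fold higher at pH 5.5 in both strains. A further 5 runs, 19 genes in all, were lower in both. Shuffled orders gave at most 2 and 1 such runs. With runs of at least 5 genes, 2 runs, 10 genes in all, were higher in both strains and 0 were lower. Shuffled orders gave 0 runs of that length in either direction.

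**Figure D2:**
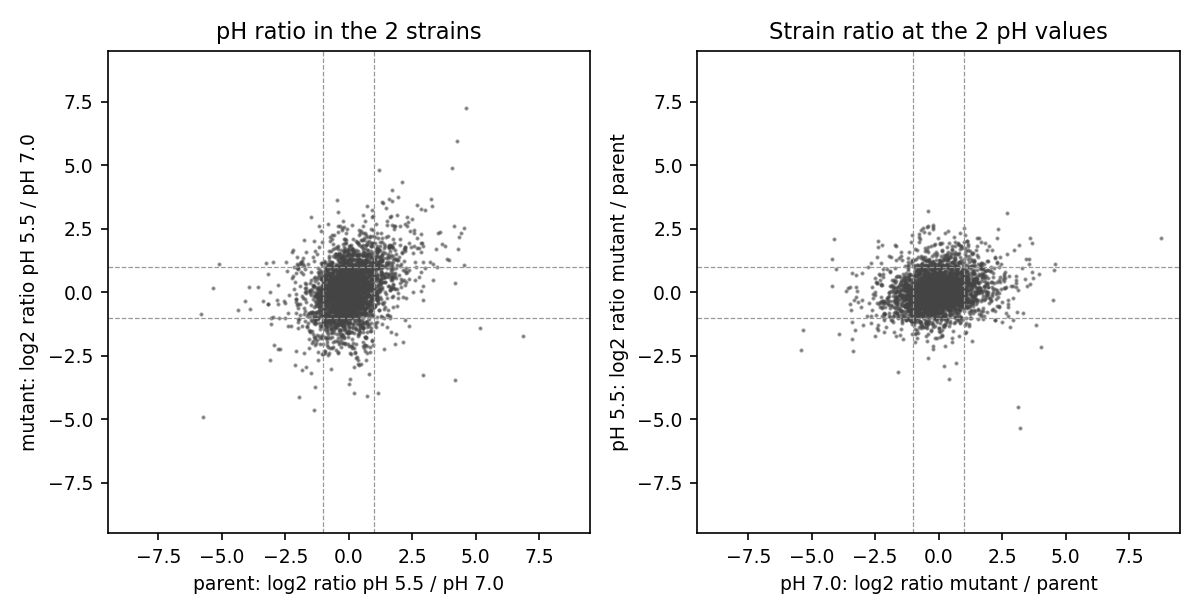
Each point is 1 of the 3122 tested genes never listed at 0, plotted by log2 ratio of FPKM + 1. Left, pH 5.5 over pH 7.0 in the parent (horizontal) and the mutant (vertical), r = 0.34; right, mutant over parent at pH 7.0 (horizontal) and at pH 5.5 (vertical), r = 0.18. Dashed lines mark 2-fold. The right-hand cloud is narrower vertically than horizontally, with SDs of 0.72 at pH 5.5 and 1.05 at pH 7.0.

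Averaged over the strains, 8 genes passed the test for a pH effect in the additive limma fit, 7 higher and 1 lower at pH 5.5. Of the 8, 2 were listed at 0 in both pH 7.0 libraries. The other 5 higher genes lay between 10.2-fold and 61.3-fold above pH 7.0. Among them gene2708, a very abundant transcript, rose from 20304 to 336644 FPKM in the parent and from 6466 to 190521 FPKM in the mutant, with a mean log2 change of 4.47 (SE 0.39, limma adjusted p = 0.0143). The transcript of gene223 rose from 87.91 to 1694 FPKM in the parent and from 76.79 to 4787 FPKM in the mutant, a mean log2 change of 5.10 (SE 0.52, limma adjusted p = 0.0246). The 1 gene that fell was gene3216. It stood at 503.2 FPKM at pH 7.0 and 8.407 FPKM at pH 5.5 in the parent, and at 459.3 and 14.36 FPKM in the mutant, a log2 change of -5.32 (SE 0.48, limma adjusted p = 0.0143). The next lower gene, gene2288, had 818.1 and 552.8 FPKM at pH 7.0 in parent and mutant, and 116.5 and 116.2 FPKM at pH 5.5, but did not pass (log2 change -2.52, SE 0.43, limma adjusted p = 0.107).

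At an unadjusted limma p under 0.05, 422 of 3141 genes showed a pH effect. By chance 157 are expected, if the moderated p-values hold with 1 residual and 5.51 prior degrees of freedom. In the simulation, 15 unchanged genes were called for pH beside 84 of 100 genes changed by 2 on the log2 scale. That simulation called many more genes, so its false calls give no number for the 8 genes here, which may still include unchanged ones. The number passing depended on the processing: 54 genes passed with median-of-ratios scaling and 62 with upper-quartile scaling, but 4 with the scaling that leaves out the 10 most abundant genes, 5 without the trend and 1 without the filter on low values. All 8 genes were among those 54 and those 62. The fit without the filter also includes genes listed at 0 in every library, whose values have no spread. Their part in its lower count was not tested. With no filter, neither gene2708, gene223 nor gene3216 passed, and gene223 also did not pass with the scaling that leaves out the 10 most abundant genes.

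The second question was how the acid-tolerant mutant differed from its parent at the same pH. At pH 7.0, 421 genes were at least 2-fold higher in the mutant and 445 at least 2-fold lower, or 27.6% of those tested. At pH 5.5 the strains were closer, with 281 genes higher and 179 lower, or 14.6%. The SD of the log2 strain ratio over genes never listed at 0 was 1.05 at pH 7.0 and 0.72 at pH 5.5. At pH 7.0, 9 runs of at least 5 successive genes were higher in the mutant and 16 runs, holding 100 genes, were lower. At pH 5.5 there was 1 higher run, of 8 genes, and 3 lower runs, holding 17 genes. At pH 7.0, 48.6% of the genes that differed were higher in the mutant, and 59.0% with upper-quartile scaling, so the prevailing direction there depended on the scaling. That scaling shifts all these ratios by nearly one amount, and it moved their median log2 from -0.066 to 0.065. Weakly expressed genes were on the whole higher in the mutant: in the lowest of 10 equal groups by mean level, the median ratio was 1.32-fold at pH 7.0 and 1.4-fold at pH 5.5. Each ratio compares 1 library with 1 library.

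Fewer genes differed between the strains in the same way at both pH values. At least 2-fold higher in the mutant at both were 72 genes, against 37.7 for independent lists, and at least 2-fold lower at both were 47, against 25.4. These were 1.91 and 1.85 times the numbers for independent lists. The pH lists gave 2.76 times for higher genes and 1.91 times for lower genes. Opposite differences of at least 2-fold were seen for 53 genes, against 63.8. The strain ratios at the 2 pH values correlated at r = 0.13 (Spearman rho = 0.19) across genes. In the same 3 groups by mean level it was 0.12, 0.13 and 0.09, from the lowest to the highest.

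In the additive limma fit, 0 genes passed for a strain effect averaged over pH, with a smallest adjusted p of 0.636. At an unadjusted limma p under 0.05 there were 237 of 3141 genes, where 157 are expected by chance under the same condition on the p-values. Without the trend, limma also called 0. The fit with no filter on low values includes genes listed at 0 in every library. It called 3 genes, 1 higher and 2 lower in the mutant. The genes with the smallest p are therefore given as values. The transcript of gene122 was at 213.6 FPKM in the mutant and 32.17 FPKM in the parent at pH 7.0, and at 32.62 and 2.858 FPKM at pH 5.5 (log2 difference 2.91, SE 0.51). The transcript of gene718 was at 1914 FPKM in the mutant and 534.9 FPKM in the parent at pH 7.0, and at 2138 and 550.3 FPKM at pH 5.5 (log2 difference 1.90, SE 0.39). On the lower side, gene3267 was at 54.22 FPKM in the mutant and 563.5 FPKM in the parent at pH 7.0, and at 55.36 and 279.6 FPKM at pH 5.5 (log2 difference -2.83, SE 0.47).

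**Figure D3:**
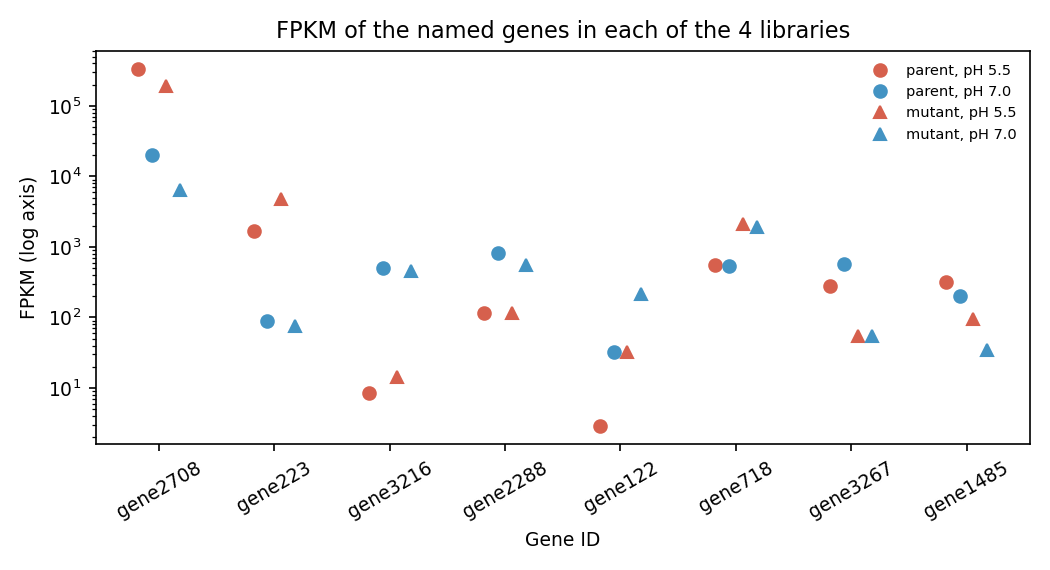
FPKM on a log axis of the 8 genes given by ID, 1 point per library (circles, parent; triangles, mutant; red, pH 5.5; blue, pH 7.0; no replicates). For gene2708 and gene223 both red points lie above both blue points, and for gene3216 and gene2288 below. For gene718 and, by a narrow margin, gene122 both mutant points lie above both parent points. For gene3267 and gene1485 both mutant points lie below both parent points.

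Whether stretches of neighbouring genes were lost or gained in expression in the mutant was asked because its genome had been shuffled. No run of at least 5 successive genes was at least 4-fold lower, or at least 4-fold higher, in the mutant at both pH values (0 runs). With a 2-fold threshold there was 1 run, of 5 genes beginning with gene1485, which was chosen for mention after its values were seen. Its members were 4.38-fold to 5.73-fold lower in the mutant at pH 7.0 and 2.11-fold to 3.3-fold lower at pH 5.5. For gene1485 the level was 34.72 FPKM in the mutant and 203.7 FPKM in the parent at pH 7.0, and 95.33 and 316.9 FPKM at pH 5.5. None of 100 shuffled gene orders gave such a run (0 runs). Shuffling also removes the correlation between neighbouring genes, which was present in every comparison, with r from 0.37 to 0.52. The shuffles therefore cannot tell whether a run comes from the shuffled genome of the mutant. With runs of at least 3 genes at the 2-fold threshold, 2 runs, 6 genes in all, were higher in the mutant at both pH values, against at most 1 in shuffled orders, and this run of 5 was the only lower one.

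The third question was whether the response to pH differed between the strains. The pH ratio was at least 4-fold higher in the mutant than in the parent for 132 genes and at least 4-fold lower for 122, together 254 of 3141. Among genes never listed at 0, the numbers were 125 and 114. With 1 library in each of the 4 groups this difference leaves no residual degree of freedom, and it is given as a count of values without a test.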

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

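Opposite responses of single genes drew attention, and the tests in this part were chosen after the results were seen, except the number of libraries per group. At least 2-fold higher at pH 5.5 in one strain and at least 2-fold lower in the other were 55 genes. At least 2-fold higher in the mutant at one pH and at least 2-fold lower at the other were 53 genes, where independent lists would give 63.8. With 1 library per group, neither difference between strains nor that between pH values was tested.

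The strains were further apart at pH 7.0 than at pH 5.5. More independent noise per gene in one of the pH 7.0 libraries would raise the spread of the ratio. It would not raise the covariance between genes next to each other in ID order. That covariance was 0.579 at pH 7.0 and 0.196 at pH 5.5, a difference of 0.383 (95% block bootstrap interval 0.287 to 0.498), which argues against such noise as the whole cause. Noise of weakly expressed genes is also argued against, because over the 1561 more abundant genes the SD was 0.93 at pH 7.0 and 0.68 at pH 5.5, a difference of 0.25 (95% interval 0.16 to 0.35). Among what stays open are the state of a single culture, such as its exact stage of growth, and any other difference that acts on many genes of 1 library together. These cannot be told apart from a strain difference that depends on pH because each group held 1 library.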

How the results depend on the processing

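The alternatives were fixed before the data were examined, except those that leave out genes listed at 0. Each group held 1 library, so no replicate number could serve as a block (the additive fit takes strain as the block for pH and pH as the block for strain), and leaving out a library leaves that fit no residual degree of freedom. Of 88 alternative values of the 11 counts of ratios, 85 stayed within 1.5 times the reported count. The other 3 came from scaling to the total without the 10 most abundant genes, which gave 365 genes higher and 606 lower at pH 5.5 in the mutant and 499 lower in the parent. Since that scaling lowers the pH ratios of a strain by nearly one amount, this follows from its construction. The additive fit for pH was less stable: 5 genes without the trend, 4 with the scaling without the 10 most abundant genes, 1 with no filter, 54 with median-of-ratios scaling, 62 with upper-quartile scaling, and 98 (81 higher, 17 lower) with median-of-ratios scaling and no gene listed at 0, which kept 6 of the 8. The 2 genes not kept there were listed at 0 in some library and so were left out before that fit. The fit with no filter also includes genes listed at 0 in every library. The cause of the differing counts was not tested. The strain effect gave 3 genes with no filter and 0 under the other 8 alternatives. Runs of neighbouring genes numbered 1 with the 2-fold threshold and, at the 4-fold threshold, 0 with runs of at least 3 genes and 0 with median-of-ratios scaling. The 8 genes given by ID kept their direction under all 9 alternatives of the fit; gene2288 passed under 3 of them. The gene lists were not run because no names were at hand. Depth is unknown and limits weakly expressed genes most.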

Other observations

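The weakly expressed genes differed between the strains in one direction at both pH values. With the genes never listed at 0 in 10 equal groups by mean level, 207 of 313 in the lowest group (median 20.15 FPKM) were higher in the mutant at pH 7.0 and 243 of 313 at pH 5.5, with median ratios of 1.32-fold and 1.4-fold. In the highest group, 120 of 313 and 112 of 313 were higher in the mutant, with median ratios of 0.81 and 0.85.

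The tests below were chosen after the result was seen, except the one over blocks of ID numbers. One hypothesis is that a few chromosomal regions carried the difference. It is argued against, because 10 of 10 blocks of ID numbers had a median ratio above 1 at both pH values among these weakly expressed genes. Another is that the same small amount of background, for example from residual DNA, was added to every gene in the mutant libraries. The median difference at pH 7.0 was 4.465 FPKM in the lowest group, 4.498 in the second and 4.489 in the third, although the interval of the last (-2.626 to 12.51) includes 0. At pH 5.5 it was 5.732 FPKM (4.777 to 7.107) in the lowest group, 4.071 (1.12 to 6.447) in the second and 1.138 (-2.021 to 5.039) in the third. A constant alone would give equal values in every group, and they were not equal: the next group at pH 7.0 was at -10.07 FPKM (-22.8 to 0.239), and the highest groups were at -253.7 FPKM at pH 7.0 and -315.7 FPKM at pH 5.5. Because FPKM is relative to the library's total, added background would also lower all other values by a common factor, and that combination was not fitted. The background hypothesis and a true difference in weak transcription therefore cannot be told apart here.

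Several abundant genes were listed at exactly 0 in 1 or more libraries. Of 546 genes that reached 1000 FPKM in some library, 9 were at exactly 0 in another, and 1 lay between 0 and 10 FPKM in its lowest library. One of the 9 was the most abundant entry of the table, at 900372 FPKM in the parent at pH 5.5, 185650 and 89744 FPKM in the parent and mutant at pH 7.0, and 0 in the mutant at pH 5.5. Zeros with almost no small values beside them are what failed estimates printed as 0 would give, and this may hold for very short genes, whose lengths were not used here. Some of the 9 followed pH in both strains, however. One stood at 27673 and 33563 FPKM at pH 5.5 in parent and mutant, and at 0 in both pH 7.0 libraries. Another stood at 9905 and 10259 FPKM at pH 5.5, and at 0 and 516.7 FPKM at pH 7.0. Others of the 9 did not follow pH. A failed estimate and a true absence cannot be told apart here. Of the 9, 2 shared exactly the same value in 2 libraries (3962 FPKM in the parent and 7979 FPKM in the mutant at pH 5.5), as near-identical copies that split reads would; for the other 7 no such partner was found, which leaves that explanation open.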
